A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

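The deposited values describe 23 mutation accumulation lines of Saccharomyces cerevisiae, 1 column per line. Per the labels, unsynchronized cultures in log phase were grown overnight in YPD at 30 °C with shaking to an OD600 of about 1.0 and frozen in cold ethanol. Total RNA was extracted with the RNeasy kit, and cDNA was made from 15 μg of RNA with SuperScript III. Each sample was labelled with one Alexa Fluor dye and hybridized to a 2-channel spotted-oligo glass array with cDNA of strain YPS183 (grown to an OD600 of 1.1), labelled with another. The common reference design had no dye swap, and the design text names 2 biological replicates per strain, but whether a column averages them is not given in the sources used here.

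The authors normalized the log ratio of the 2 channels of each array, and the deposited table was read as log2, the usual base for such tables, since neither the base nor the numerator is given in the sources used here. Background correction, the normalization method, spot filtering, the filling of missing values and the averaging of spots are not given in the sources used here either. The table had 6334 features with no missing value in any column. Column medians lay between -0.018 and 0.018 and column SDs between 0.245 and 0.583, so columns were centred but not scaled to a common spread. Signal over background was not used here, since the table holds ratios alone, so the precision of a single ratio was not measured. Values entered every test as deposited, and signs were kept as deposited.

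Features were paired with gene symbols and chromosomes of the R64 reference annotation by their systematic names: 5623 exactly, 194 after a dropped hyphen was restored and 7 by a synonym, and 510 were not matched. Unmatched features stayed in all tests over the whole table and were not put in lists. In the chromosome tests each feature, matched or not, was placed by the chromosome that its systematic name gives. The lines were treated as 1 group, and no second group or batch is given in the labels.

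The mean over lines was tested against 0 with limma 3.58.1 in R 4.3.3 (intercept alone, eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over all features and an adjusted p threshold of 0.05. Spread between lines was tested by an F test of each variance on the prior that squeezeVar fits with robust = TRUE. A second form, chosen after the data were seen, set each variance against the prior variance as fixed, by a chi-square test. Departures of single lines were tested by limma with an intercept and a term for 1 line, for each of 23 lines, adjusted over all features and lines together, and called at an adjusted p under 0.05 with an absolute difference of 1 or more from the mean of the other lines. A single column was assumed to vary like the other lines, and the table has no replicate of a line with which to check it.

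In all, 37 gene lists were written before the data were examined, and 36 had at least 4 measured genes. None of the 10 genes of the mitochondrial genome was measured. List means were tested by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry. The median SD of a list was set against 10000 random lists matched in size and in quintile of the absolute mean, two-sided, and its mean pairwise Pearson correlation against 10000 random lists, one-sided. Where a count adjusted over the list alone is given, the adjustment was repeated within that list. Chromosome shifts were medians over genes of the difference from the other lines, against 10000 random gene sets in the same line, called at an adjusted p under 0.05 and an absolute median of 0.3 or more. Relations between list medians across lines were tested with 100000 permutations, with 8 relations adjusted together. These relations were picked from the possible pairs of lists and were not among the planned tests, and 1 used the Ty list described below. The variance on the leading component was set against 100 shuffles. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A list of 67 Ty reading frames was written after the departures were seen.

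Genes were named by a rule fixed before the data were examined. For the mean it took called genes with the same sign in every line (the 12 highest and the 12 lowest means), and 4 genes met it. For spread it took the 24 called genes with the highest SD, and none was called. For departures it took the 15 largest pairs and the 3 largest of each of the 3 lines with most calls, where lines 8 and 40 tied. For each list it took up to 4 called members with the largest absolute mean and up to 4 with the highest SD, with all measured members of the mating-type and marker lists. Other named genes were chosen after their values were seen.

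The steps were tested on simulated data with 6334 features and 23 columns. The test of the mean recovered 43 of 50 changes of 0.3, 49 of 50 of 0.6 and 100 of 100 of 1, and list means shifted by 0.2 were recovered in 10 of 10 lists. The planned test of spread recovered 0 of 50 genes with a doubled SD and the chi-square form 48 of 50. The test of departures recovered 11 of 50 of size 1 and 69 of 100 of size 2. The list tests recovered 4 of 5 raised spreads and 5 of 5 shared movements, and the chromosome test 3 of 3 raised chromosomes. False calls numbered 11 for the mean, 12 for the chi-square form, 7 for departures, and 1 each for list spread and covariation. There were 0 for the planned spread test, list means and chromosomes. Apart from the changes put in, simulated genes moved independently, while the leading component of the real table held 44.0% of its variance. For the chi-square form all unchanged genes had the same SD, where real SDs ran from 0.138 to 0.687 (5th to 95th percentile). These false-call counts therefore do not carry over to the real table.

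The alternatives were centring each array on its median, scaling to a common median absolute deviation (MAD), quantile normalization, leaving out 1 line, robust eBayes, array weights, a Wilcoxon signed-rank test, a prior without robust fitting, removal of the leading component, leaving out the 2 arrays with the largest residual variance, other size thresholds, a robust z of 6 or more, an estimated correlation, fry, no matching on the mean, Spearman correlations, and means in place of medians. Chosen after the data were seen were averaging lines 1 and 45, leaving out unmatched features, and leaving out line 10 from the list spread, covariation, chromosome and similarity results. Signal intensities, the print layout and the platform's annotation were not used here. Values of 2 genes that the naming rule selects are not reported here.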

Results

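The data were log ratios of transcript abundance in 23 mutation accumulation lines of budding yeast, which are lines propagated separately so that spontaneous mutations gather in each. Every line was set against 1 reference strain, YPS183, in a column of its own. Each column gave 6334 values with none missing, and 5824 of them were paired with a current gene. The lines formed a single group, labelled 19-1 to 19-50 with gaps and called here by the number after the hyphen, so the design raised 2 questions: which genes differed from the reference over the lines, and which differed from line to line. No column held the ancestor of the lines, and the labels do not say how YPS183 relates to it. A mean that differs from 0 therefore cannot be assigned to mutation accumulation rather than to the strain or culture of the reference. Array medians lay between -0.018 and 0.018, array SDs between 0.245 and 0.583, and single values between -4.22 and 4.60. The labels state neither the numerator of the ratio nor the base of its logarithm, so values were read as log2 and are placed on the positive or negative side as deposited, with no direction between line and reference. One column stood for a line, and whether it averages replicates is not stated, so line, culture and array differences were not separated.

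Over the 23 lines, most called genes of amino acid synthesis were negative. ARG1 (YOL058W) and ARG4 (YHR018C), which carry out the last steps of arginine synthesis, were negative in every line, with means of -0.79 ± 0.09 and -0.63 ± 0.08 (SE, n = 23, limma adjusted p = 4.86e-06 and 4.53e-05). Among 62 measured synthesis genes under the general amino acid control activator Gcn4, 33 had a mean that differed from 0, 29 negative and 4 positive. Adjusted over the list alone, 39 did, 35 negative and 4 positive. GDH1, a glutamate dehydrogenase that assimilates ammonium, had a mean of -0.65 ± 0.10, and HIS1, the first enzyme of histidine synthesis, had -0.62 ± 0.12. The 4 positive members were the glycine cleavage genes GCV1 (0.37) and GCV2 (0.34) and the serine synthesis genes SER3 (0.29) and SER1 (0.20). The Gcn4 list as a whole lay on the negative side by camera with a preset correlation (adjusted p = 7.07e-11) and by fry (adjusted p = 0.00821), with adjusted p = 0.481 with an estimated correlation. In the sulfur amino acid list, 8 of 31 genes were called, 7 negative and 1 positive, and 10 adjusted over the list alone. Its negative members included the permeases MMP1 (-0.54 ± 0.07) and MUP1 (-0.52 ± 0.10), MET17 (-0.50 ± 0.09) and CYS3 (-0.44 ± 0.09), and its positive member was the methionine synthase MET6 (0.37). That list was negative by camera (adjusted p = 0.000651) and by fry (adjusted p = 0.00413), with adjusted p = 0.481 with an estimated correlation.

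Genes of carbon use fell on both sides. ADH2, the alcohol dehydrogenase repressed by glucose, had a mean of 0.66 ± 0.11 (SE, n = 23) and was positive in 22 of 23 lines, and the gluconeogenesis genes PCK1 (0.41 ± 0.10) and FBP1 (0.39 ± 0.08) and the acetate transporter gene ADY2 (0.36 ± 0.08) were positive too. In the list for the glyoxylate cycle, gluconeogenesis and acetate use, 8 of 26 genes were called, all positive, and 11 adjusted over the list alone. The list was positive by camera (adjusted p = 1.2e-06) and by fry (adjusted p = 0.0414), with adjusted p = 0.603 with an estimated correlation. Nuclear genes of the respiratory chain and ATP synthase were on the other side, with 8 of 38 called, all negative, among them the ATP synthase subunits ATP1 (-0.60 ± 0.13) and ATP2 (-0.45 ± 0.11) and the cytochrome oxidase subunit COX8 (-0.46 ± 0.11). Adjusted over the list alone, 17 were called, 16 negative and 1 positive. Camera placed the list on the negative side (adjusted p = 3.05e-07), as did fry (adjusted p = 0.0384), with adjusted p = 0.603 with an estimated correlation. Of 18 tricarboxylic acid cycle genes, 3 were called, all negative, among them CIT1 (-0.52 ± 0.15) and IDP1 (-0.30 ± 0.05), and 5 adjusted over the list alone. That list was negative by camera (adjusted p = 0.0209), with adjusted p = 0.898 with an estimated correlation and 0.263 by fry.

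The called hexose transporter genes were negative. The hexose transporter genes HXT6 (-0.78 ± 0.16), HXT3 (-0.74 ± 0.11) and HXT7 (-0.53 ± 0.10) were the 3 called of 20, and 4 were called adjusted over the list alone, 3 negative and 1 positive. In glycolysis and fermentation, 8 of 24 genes were called, 6 negative and 2 positive, and 9 adjusted over the list alone. The hexokinase gene HXK2 had a mean of -0.64 ± 0.12, while the alcohol dehydrogenase genes ADH1 (0.62 ± 0.10) and ADH3 (0.45) were the positive pair. Neither list was called by camera (adjusted p = 0.104 and 0.441). Of 60 genes of the environmental stress response, the targets of Msn2 and Msn4, 7 were called negative and 2 positive, and 12 were called adjusted over the list alone, 9 negative and 3 positive. The negative ones included TSL1 (-0.71 ± 0.17) and TPS2 (-0.69 ± 0.18) of trehalose synthesis and the glycogen synthase gene GSY2 (-0.56 ± 0.16). The stress list was negative by camera (adjusted p = 0.0330), with adjusted p = 0.909 with an estimated correlation and 0.671 by fry. The camera calls of the stress and tricarboxylic acid lists were lost under quantile normalization (adjusted p = 0.0614 for each) and when 1 of several lines was left out: 2, 4, 6, 10, 19, 22, 25 or 40 for the stress list (0.0728 to 0.396), and 4, 6, 10, 22, 25 or 40 for the tricarboxylic acid list (0.0534 to 0.133).

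The called mating genes were positive. STE2 (YFL026W), the receptor for alpha-factor that is made in a cells, had a mean of 0.79 ± 0.23 (SE, n = 23, adjusted p = 0.0318) and was positive in 18 of 23 lines. It was the 1 called among 7 a-specific genes, and 6, all positive, were called adjusted over the list alone. Camera placed the a-specific list on the positive side (adjusted p = 0.00790), with adjusted p = 0.603 with an estimated correlation and 0.0603 by fry. Lines 10 and 40, described further on, weighed on these means. Over the other 21 lines the means of the 7 genes ran from -0.03 (ASG7) to 0.51 (STE2). Of 29 haploid-specific and pheromone-response genes, 4 were called, all positive: STE4, the pheromone G protein beta subunit (0.53 ± 0.14), RDH54 (0.47 ± 0.15), RME1 (0.28 ± 0.07) and the transcription factor gene STE12 (0.24 ± 0.07). Adjusted over the list alone, 13 were called, all positive, and the list was positive by camera (adjusted p = 0.000111) and by fry (adjusted p = 0.00912), with adjusted p = 0.481 with an estimated correlation. Among 7 alpha-specific genes, HMLALPHA1 was called (0.12 ± 0.04), 2 were adjusted over the list alone, and the list was not called (camera adjusted p = 0.193). Whether the spots of HMLALPHA1 and MATALPHA1, or of HMLALPHA2 and MATALPHA2, measure separate transcripts was not tested, here or for single lines below.

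The called genes of the histone list and of 2 subtelomeric lists were negative. HTB2 (-0.55 ± 0.14), HHF1 (-0.50 ± 0.13), HTB1 (-0.47 ± 0.12) and HTA1 (-0.45 ± 0.14) were the 4 called of 10 histone genes, and 4 were called adjusted over the list alone. The camera call of the list (adjusted p = 0.000390) had adjusted p = 0.717 with an estimated correlation and 0.0912 by fry. Of 24 seripauperin (PAU) genes, a family of cell-wall proteins at chromosome ends, 11 were called, all negative, led by PAU20 (-0.32 ± 0.05) and PAU17 (-0.27 ± 0.06), and 15 adjusted over the list alone, all negative. The PAU list was negative by camera (adjusted p = 9.66e-10) and by fry (adjusted p = 0.00912), with adjusted p = 0.481 with an estimated correlation. In the list of 26 COS, Y-prime and AAD genes, the 4 called were the Y-prime helicase genes YRF1-4, YRF1-6, YRF1-2 and YRF1-7, with means from -0.32 to -0.18, and 4 were called adjusted over the list alone. Its camera call (adjusted p = 0.0214) had adjusted p = 0.898 with an estimated correlation and 0.204 by fry, and was lost under scaling to a common median absolute deviation (adjusted p = 0.0659), under quantile normalization (adjusted p = 0.0854) and without line 4, 10 or 40 (0.0681 to 0.112). Members of the PAU and YRF1 families are nearly identical in sequence, so their spots are not independent.

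Few ribosomal protein genes were called, mitochondrial ones positive and cytosolic ones negative. Mitochondrial ribosomal protein genes had 7 of 71 called, all positive, among them MRPL10 (0.27 ± 0.09) and MRPL40 (0.26 ± 0.05), and 9 adjusted over the list alone. Camera called that list positive (adjusted p = 5.72e-06), with adjusted p = 0.898 with an estimated correlation and 0.204 by fry. Of 137 cytosolic ribosomal protein genes, 2 were called, RPL41B (-0.43 ± 0.12) and RPL4A (-0.29 ± 0.05), and 1 adjusted over the list alone. Camera called the list negative (adjusted p = 0.000413), with adjusted p = 0.909 with an estimated correlation and 0.593 by fry. The mean of this list was small beside its spread between lines, described further on.

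The remaining lists were not called by camera, with adjusted p from 0.189 to 0.771, and held scattered called genes. The metallothionein genes CUP1-2 (-0.87 ± 0.14) and CUP1-1 (-0.84 ± 0.16) and the copper transporter gene CTR1 (0.33 ± 0.08) were among 4 called of 15 copper and zinc genes, with 8 adjusted over the list alone. Whether the spots of CUP1-1 and CUP1-2 measure separate transcripts was not tested. Nor was it for HXT6 and HXT7 above or for ENA1 and ENA2 below. THI4 of thiazole synthesis (-0.87 ± 0.21), PDC5 (-0.58 ± 0.18) and THI21 (0.32 ± 0.10) were the 3 called of 18 thiamine genes, over all genes and over the list alone. Iron uptake genes FET3 (-0.43 ± 0.12) and FTR1 (-0.39 ± 0.11) were the 2 called of 30 in the iron regulon, as they were over the list alone. Of 19 adenine and one-carbon genes, 3 were called, all positive (GCV1, GCV2 and ADE1), and 4 over the list alone. Ammonium permease MEP1 (-0.53 ± 0.14), GLN1 (-0.48 ± 0.15) and ornithine aminotransferase CAR2 (0.41 ± 0.05) were the 3 called of 32 nitrogen catabolite genes, with 5 over the list alone. The wall protein genes HPF1 (-0.72 ± 0.12) and TIP1 (0.61 ± 0.14) were among 5 called of 21 flocculation and surface genes, with 5 over the list alone. The weak-acid pump gene PDR12 (0.61 ± 0.14) was the 1 called of 18 drug resistance genes.

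Cell-cycle and other lists held called genes too. G1/S genes had 5 of 61 called, 4 negative, led by GAS1 (-0.59 ± 0.14) and ELO1 (-0.46 ± 0.10), and M/G1 genes had 5 of 34, 4 positive, with the cyclin gene CLN3 negative (-0.32 ± 0.06). The M/G1 count was 7 adjusted over the list alone and the G1/S count stayed at 5. CDC20 (-0.27 ± 0.05) was the 1 called of 36 G2/M genes, SPO21 (-0.13 ± 0.04) of 41 meiosis and sporulation genes, and PGM2 (-0.59 ± 0.17) of 21 galactose and maltose genes. Ribosome biogenesis had 4 of 91 (TIF6, -0.40 ± 0.07, first) and 3 over the list alone, the Hsf1 chaperones 3 of 24 and 4, the phosphate genes 3 of 18 and 3, and the retrograde response 2 of 14 and 2. ERG5 (-0.25 ± 0.08) was the 1 called of 25 ergosterol genes, with 0 adjusted over the list alone by limma, 8 at an unadjusted p under 0.05, and fry adjusted p = 0.869. The proteasome (35 genes) and the oxidative stress list (23 genes) had 0 called by limma, with 7 and 8 genes at an unadjusted p under 0.05 and fry adjusted p = 0.889 and 0.869. Among 7 marker genes deleted in many laboratory strains, MET17 alone was called. URA3 (-0.03), LEU2 (-0.02), HIS3 (-0.02), LYS2 (-0.03), TRP1 (0.13) and ADE2 (0.16) had means not distinguished from 0. Median, mean and camera direction differed in sign for 6 uncalled lists: phosphate, iron, Hsf1, retrograde, G1/S and drug resistance, all with medians and means within 0.04 of 0.

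By limma, 584 genes had a mean that differed from 0 at an adjusted p under 0.05, 253 positive and 331 negative, and 1539 did at an unadjusted p under 0.05. An absolute mean of 1 or more was reached by 2, ENA2 (YDR039C), a sodium efflux ATPase (-1.02 ± 0.22, SE, n = 23, adjusted p = 0.00409), and RGI1 (YER067W), a gene of respiratory growth (-1.01 ± 0.24, adjusted p = 0.00910). ENA1, which neighbours ENA2, had -0.92 ± 0.22, and 60 called genes had an absolute mean of 0.5 or more. Only 4 called genes had the same sign in every line: ARG1, ARG4, YJL007C (0.93 ± 0.10, adjusted p = 1.31e-06) and YKL202W (0.86 ± 0.09), the last without a current gene. ENA1, ENA2, RGI1 and the genes of this paragraph other than those 4 were chosen after their values were seen. The test left out the spread of the reference and any dye effect, since the dyes were never exchanged, and weighting the arrays raised the count to 1298.

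Genes with a high SD from line to line included members of the stress list and genes of carbon use. SUC2 (YIL162W), the secreted invertase, had an SD of 1.48 over the 23 lines, from -4.22 in line 6 to 1.36 in line 45. In the stress list, YGP1 had an SD of 1.40, DCS2 1.37, the glycogen phosphorylase gene GPH1 1.35 and DDR2 1.34, and the lowest value of all 4 was in line 6. The maltase gene MAL32 (SD 1.16), the lactate permease gene JEN1 (1.17), the peroxisomal citrate synthase gene CIT2 (1.23) and the aldehyde dehydrogenase genes ALD3 (1.23) and ALD4 (1.17) were near them, as was STE2 (1.19). The median SD over all genes was 0.256. These genes were chosen after their values were seen, because the planned test, an F test of each variance on the prior fitted by limma, called 0 genes, with 358 at an unadjusted p under 0.05. That test had no power here, since it recovered 0 of 100 genes whose SD had been raised 4 times in simulated data. A test chosen after the data were seen set each variance against that of the typical gene. It called 2160 genes, of which 1516 were also called with the leading component removed. Such a call does not separate a noisier spot from a spread between lines. Adjusted over the list alone, the planned test called 90 of 137 cytosolic ribosomal protein genes, 36 of 60 stress genes and 9 of 18 thiamine genes, and 0 in each other list.

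Whole groups of genes varied more between lines than random lists matched on the size of their mean. Stress genes had a median SD of 0.882 where random lists had 0.359, thiamine genes 0.842 where random lists had 0.334, and cytosolic ribosomal protein genes 0.822 where random lists had 0.323 (adjusted p = 0.00144 for each, from the smallest p that the permutations allow). RPS10A (SD 1.05) and RPL25 (1.03) were among the highest of the ribosomal list, and PHO3 (1.15), THI4 (1.08) and THI13 (1.07) led the thiamine list. In all, 15 of 36 lists lay above random lists: these 3, hexose transporters (0.658), histones (0.630), adenine and one-carbon genes (0.553), tricarboxylic acid cycle (0.548), glycolysis (0.521), respiratory chain (0.507), retrograde response (0.430), oxidative stress (0.415), ribosome biogenesis (0.396), drug resistance (0.392), G1/S genes (0.326) and the proteasome (0.324). Galactose and maltose genes (0.292, adjusted p = 0.489) and the glyoxylate list (0.469, adjusted p = 0.127) were not called, but the glyoxylate list was under quantile normalization (0.480, adjusted p = 0.0228) and without matching on the mean (adjusted p = 0.000600). Meiosis and sporulation genes lay below, at 0.183 where random lists had 0.230 (adjusted p = 0.00400), and so did PAU genes, at 0.235 where random lists had 0.329 (adjusted p = 0.0111). The PAU call was lost without matching on the mean (adjusted p = 0.493), and the calls of the G1/S and retrograde lists were lost with the leading component removed (adjusted p = 0.297 and 0.0518). The proteasome call was lost without line 10 (adjusted p = 0.0854) and the oxidative stress call with centred arrays (adjusted p = 0.0632).

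**Figure D1:**
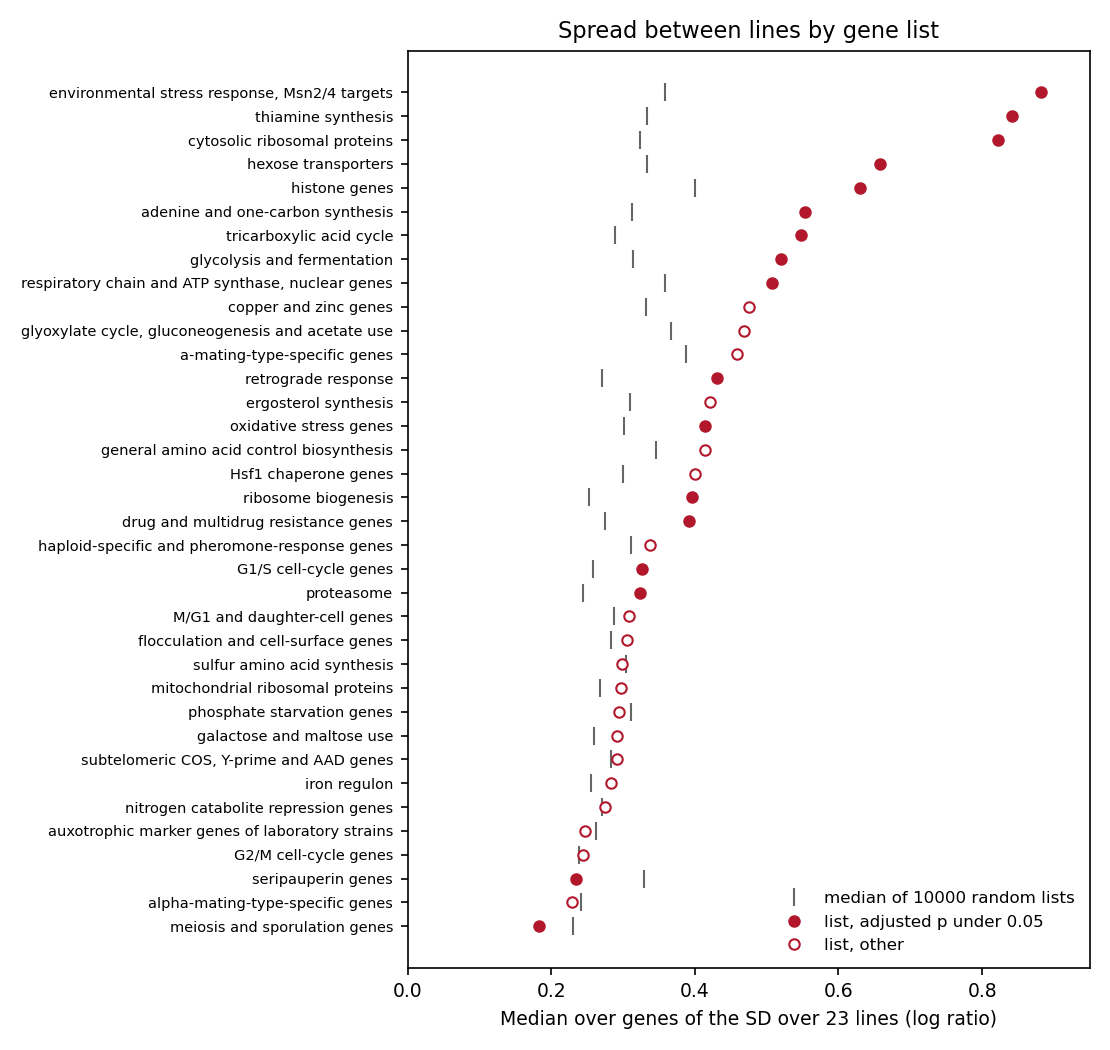
Each point is the median over the genes of a list of the SD over 23 lines, in log ratio units, and each tick the median of 10000 random lists of the same size. Filled points are lists with adjusted p under 0.05, with stress genes at 0.882 at the top and meiosis and sporulation genes at 0.183 at the bottom.

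Genes of a group also rose and fell together from line to line. The mean pairwise correlation across lines was 0.795 among ribosomal protein genes, 0.785 among histone genes, 0.700 among stress genes, 0.571 in ribosome biogenesis and 0.512 among PAU genes (adjusted p = 0.000180 for each, from the smallest p that the permutations allow). By this measure 31 of 36 lists were above random lists, and 30 of these were also above with the leading component removed. The 5 that were not were the phosphate, copper and zinc, meiosis, flocculation and marker gene lists. Correlated members of a list are not independent, which bears on every list test that presets a low correlation.

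Across lines, ribosomal protein genes ran against stress genes. The median of 137 ribosomal protein genes and that of 60 stress genes had a Pearson r of -0.640 (permutation p = 0.00111, adjusted p = 0.00111) and a Spearman rho of -0.702 (permutation p = 0.000330, adjusted p = 0.000377), and r was -0.633 without lines 10 and 40. Line 10 had medians of 1.41 and -0.93, line 44 of -1.26 and 0.84, and line 8 was positive for both, at 0.74 and 0.79. Ribosomal protein genes went with ribosome biogenesis genes (r = 0.729, permutation p = 9.00e-05, adjusted p = 0.000144; rho = 0.826, permutation p = 1e-05, adjusted p = 4.00e-05; r = 0.761 without lines 10 and 40) and with histone genes (r = 0.783, permutation p = 2.00e-05, adjusted p = 4.00e-05; rho = 0.723, permutation p = 0.000200, adjusted p = 0.000267; r = 0.778 without lines 10 and 40). Stress genes went with galactose, maltose and sucrose genes (r = 0.863, permutation p = 1e-05, adjusted p = 2.67e-05; rho = 0.898, permutation p = 1e-05, adjusted p = 4.00e-05; r = 0.904 without lines 6 and 4). They also went with the glyoxylate list (r = 0.817, permutation p = 1e-05, adjusted p = 2.67e-05; rho = 0.751, permutation p = 9.00e-05, adjusted p = 0.000144; r = 0.785 without lines 6 and 4). With the tricarboxylic acid cycle r was 0.757 (permutation p = 1e-05, adjusted p = 2.67e-05), rho was 0.737 (permutation p = 8.00e-05, adjusted p = 0.000144), and r was 0.696 without lines 6 and 4. These were 6 of 8 relations tested across lines, which were not among the planned tests. The stress list shares PGM2 with the galactose and maltose list and ALD4 with the glyoxylate list. The smallest p that the permutations could give is 1e-05, and the labels give no batch within which to repeat the relations.

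**Figure D2:**
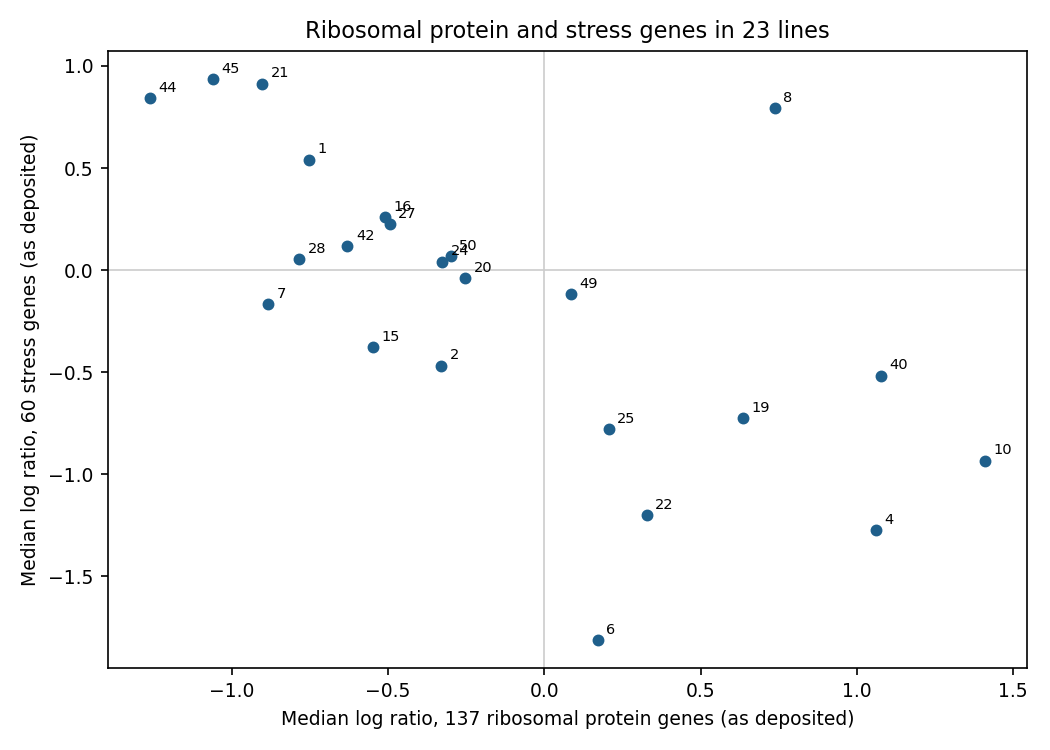
Each point is 1 of 23 lines, placed by its median log ratio over 137 cytosolic ribosomal protein genes (x axis) and over 60 stress genes (y axis), as deposited. The points run from line 44 at the upper left to lines 10 and 4 at the lower right (Pearson r = -0.640). Line 6 is lowest (-1.81) but near the middle of the x axis (0.17), and line 8 is apart at the upper right.

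Lines 10 and 40 had the highest medians of a-specific genes and of Ty retrotransposons. In line 10, STE2 had a value of 4.55, the a-factor genes MFA2 3.53 and MFA1 1.45, AGA2 1.45 and BAR1 1.28, while ASG7 had -0.13. STE6, the a-factor exporter gene, differed from the other lines by 1.34. Line 40 had 2.86 for STE2, 2.29 for MFA2, 1.53 for BAR1, 1.10 for MFA1, 1.01 for AGA2, -0.47 for STE6 and -0.24 for ASG7. The highest values of STE2 and MFA2 in the other lines were 2.12 and 1.88, both in line 25. The median difference of the 7 genes from the other lines was 1.31 in line 10 and 0.94 in line 40, above 99.99% and 100% of random lists of 7 genes. Both lines were picked by the medians of these genes, so these ranks largely restate that choice. The 7 genes also moved together (mean pairwise r = 0.457), unlike those of random lists. The next highest a-specific medians were 0.61 in line 50 and 0.59 in line 49, where 6 and 7 of the 7 genes were above the other lines, and in line 49 24 of 29 haploid-specific genes were, against 19 in line 10. No a-specific pair passed the departure test over all genes (STE2 in line 10, difference 3.93, adjusted p = 0.0820), and 5 did adjusted over the list alone. Of 67 Ty reading frames, a list drawn up after the departures were seen, 65 were above the other lines in line 10 and 58 in line 40, with median differences of 1.72 and 0.95 where the highest of 10000 random lists had 0.239 and 0.254. Ty frames are nearly identical copies, so their spots can share signal.

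In the alpha-specific list, MF(ALPHA)1, which encodes the alpha-factor pheromone, differed by 2.25 in line 40 (adjusted p = 2.64e-06) and by -0.22 in line 10. The differences of SAG1 and STE3 were 0.62 and 0.52 in line 40 and 0.04 and -0.23 in line 10, and those of HMLALPHA2, MATALPHA2, HMLALPHA1 and MATALPHA1 were 1.05, 0.66, 0.46 and 0.03 in line 10. Among the haploid-specific genes, 5 were called in line 10: FAR1 (YJL157C), a cell-cycle arrest factor of the pheromone response (difference 3.06), RDH54 (2.70), the mating-type switching endonuclease gene HO (2.18), NEJ1 (1.92) and the kinase gene FUS3 (1.71). With the leading component removed HO and NEJ1 kept the call (adjusted p = 0.000587 and 0.0482), while FAR1 (difference 2.31, adjusted p = 0.110), RDH54 (1.96, 0.0781) and FUS3 (1.44, 0.0775) lost it. AGA1 was called in line 40 (1.64), so 6 pairs of this list passed over all genes and 10 adjusted over the list alone. Large uncalled differences in line 10 were STE4 (2.29), GPA1 (2.10), SST2 (1.33), STE5 (1.09), RME1 (1.01) and STE12 (0.98). Other members in line 10 had differences of 0.26 (AGA1) or less: FUS1 (-0.04), FUS2 (-0.43), PRM1 (-0.80), FIG1 (-0.14), FIG2 (-0.03), KAR4 (0.02), KAR5 (-0.15), MSG5 (-0.03), PRM4 (-0.45), PRM5 (-0.34) and GPG1 (-0.92). The remaining members STE18, AXL1, DDC1, PRM2, PRM3 and PRM6 lay between 0.06 and 0.65. Across all 23 lines, the a-specific and haploid-specific medians correlated (r = 0.676, permutation p = 0.000920, adjusted p = 0.00105; rho = 0.769, permutation p = 6.00e-05, adjusted p = 0.000144), with r = 0.776 without lines 10 and 40. The a-specific and Ty medians had r = 0.848 (permutation p = 0.000360, adjusted p = 0.000480) and rho = 0.478 (permutation p = 0.0216, adjusted p = 0.0216), but r was 0.229 without lines 10 and 40, so that relation rests on those lines.

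**Figure D3:**
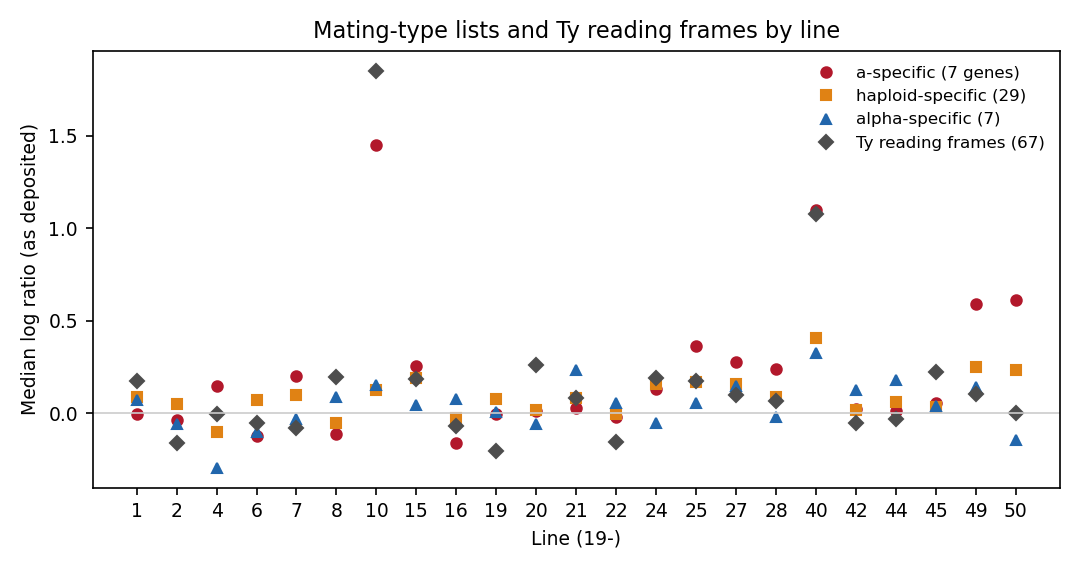
Points are medians of the log ratio, as deposited, over 7 a-specific, 29 haploid-specific and 7 alpha-specific genes and 67 Ty reading frames, for each of 23 lines. Line 10 has medians of 1.45 for a-specific genes and 1.85 for Ty frames, and line 40 has 1.10 and 1.08.

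Line 10 also carried 68 of the 99 called gene-line pairs, 64 positive and 4 negative. With the leading component removed it carried 47 of 136, with 42 of the 68 shared, and line 8 went from 6 to 45. Line 10 was also the most dispersed column, with the highest SD (0.583), the largest share of the residual variance (10.96%) and the lowest array weight (0.379). They included 37 Ty frames and 11 cytosolic ribosomal protein genes, among them RPL36B (difference 3.20), RPL29 (3.07), RPL36A (2.92), RPS26A (2.83) and RPL34A (2.73). Of these 11, 6 kept the call with the leading component removed, and RPL36B (2.21, adjusted p = 0.0649), RPS26A (1.95, 0.0617) and RPL34A (1.87, 0.0664) were among those that lost it. The largest difference was that of YLR162W, 4.91 (value 4.60, mean of the other lines -0.31, adjusted p = 0.00115), and RXT2, a subunit of a histone deacetylase complex, differed by 3.04. Without line 10 the count was 33. It was 43 with arrays scaled to a common median absolute deviation, with 23 pairs shared, and 52 after quantile normalization, with 18 shared. In simulated data the test recovered 69 of 100 departures of 2 and 11 of 50 departures of 1, so smaller ones were mostly missed.

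The other lines had 31 called departures. Line 8 had 6, all positive: the neighbouring vitamin B6 genes SNZ1 (2.66, adjusted p = 0.00163) and SNO1 (2.64), NCA3 (2.53), the reductase genes GRE2 (2.11) and ARI1 (1.39), and BNA1 of NAD synthesis (1.81). Line 19 had 7, with YLR169W, a row without a current gene (-2.45), the Ty frame YBL005W-B (-1.71) and RRG8 (-1.34) among 6 negative ones, and RRN10, an RNA polymerase I factor gene, positive (1.07). In line 24 the meiosis gene SPO22 (YIL073C) had a difference of -3.05 (adjusted p = 1.65e-10). Line 20 had ARG4 at -1.58, line 42 had VBA4 at 1.75 and MMP1 at 1.29, and line 45 had the chaperone gene SSA3 at 1.34. With the leading component removed the difference of SSA3 was 1.11 and its call was lost. Line 40 had MPC1 at 1.42, IRC16 at -1.37 and YOR338W, with a value of -1.41, besides its mating genes. Line 6 had HMRA1 at -1.04, line 22 had VBA5 at -1.02, and line 28 had AIM11 at 1.26. With the leading component removed HMRA1 (-0.78) and VBA5 (-0.92) fell under the size threshold of 1. Genes in this paragraph beyond the 15 largest pairs and the leading 3 of lines 10, 19, 8 and 40 were chosen after their values were seen. Each departure rests on 1 column, assumed to vary like those of the other lines.

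Genes of chromosome IX in lines 49 and 50, and of 3 chromosomes in line 20, were displaced as groups. The median gene of chromosome IX lay 0.31 above the other lines in line 49, where 87.1% of 224 genes were above them, and 0.26 in line 50, where 82.1% were. In line 20 the medians were -0.24 on chromosome XIII (17.0% of 501 genes above the other lines), -0.22 on chromosome VIII (20.4% of 284 genes) and -0.22 on chromosome VI (20.6% of 136 genes). All 5 had adjusted p = 0.00320, from the smallest p that 10000 random gene sets allow, as did the next largest, chromosome I in line 40 (-0.18). In line 20, 13 of 16 chromosomes had an adjusted p under 0.05, among them VII (0.11), II (0.11) and X (0.09) on the positive side. On chromosomes VI and VIII in line 20 a part of the genes lay inside random sets (-0.12 and -0.11). Only chromosome IX in line 49 also passed the size threshold of 0.3, and it fell to 0.295 with the leading component removed and with means in place of medians. Without a size threshold 67 line and chromosome pairs were called, most of them small, and the shared movement of neighbouring genes was not separated from them.

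**Figure D4:**
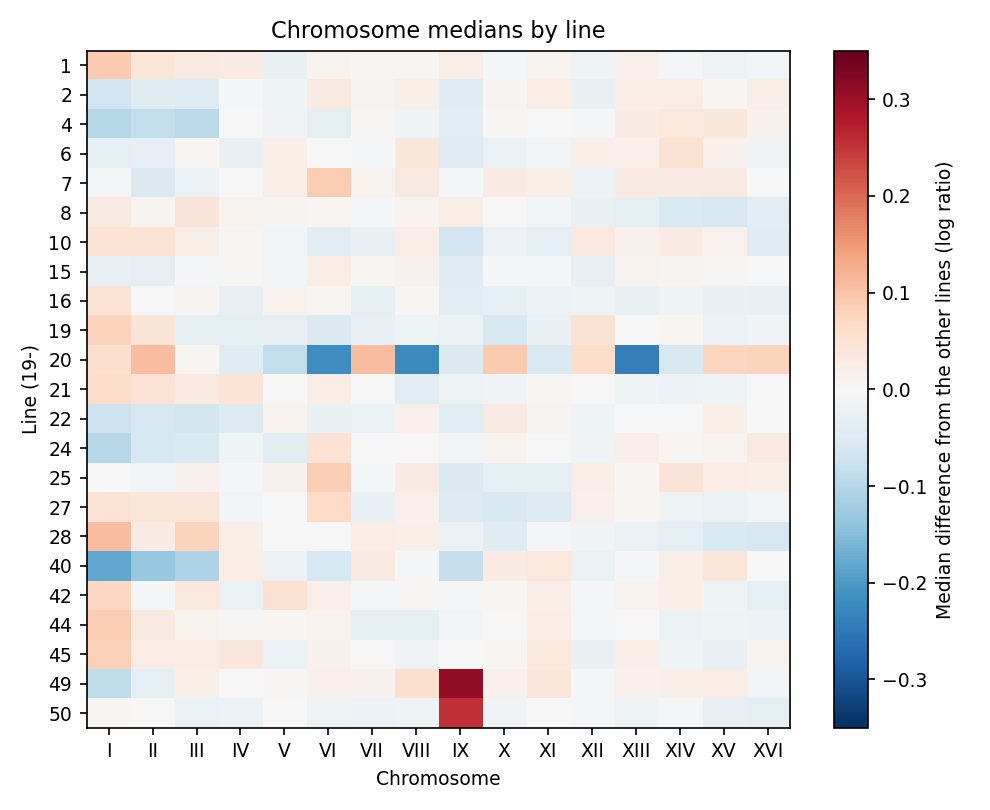
Colours give the median over the genes of a chromosome (columns) of the difference of a line (rows) from the mean of the other lines, in log ratio units. Chromosome IX is positive in lines 49 (0.31) and 50 (0.26), and chromosomes VI, VIII and XIII are negative in line 20 (-0.22, -0.22 and -0.24).

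One axis ordered the lines, from RPL and RPS genes at its positive end to stress genes at the other. The leading component of the gene-centred table held 44.0% of the variance, where 100 shuffles gave at most 5.60%, and the next components held 12.6% and 8.17%. Lines 10, 6, 4 and 22 stood at one end and lines 44, 45, 21 and 1 at the other. Of 253 pairs of lines, 28 correlated across genes below -0.3, lowest for lines 4 and 44 (r = -0.636), and the highest r was 0.899, between lines 1 and 45. These correlations are across genes, which are not independent replicates.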

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

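Chosen after the data were seen were the chi-square form of the spread test, lines 1 and 45 averaged, unmatched features left out, line 10 left out of the list spread, covariation, chromosome and similarity results, and the leading component removed for the haploid-specific calls of line 10. The count of genes with a mean different from 0 (584) was 1298 with array weights, and the cause was not tested. It lay between 467 and 768 under centring, MAD scaling, quantile normalization, robust eBayes, the Wilcoxon test, lines 1 and 45 averaged and unmatched features left out, and between 454 (without line 1) and 682 (without line 10) with 1 line left out. The planned spread test gave 0 in every setting and with any line left out, which says nothing about stability, since it had no power on simulated data. Its chi-square form (2160) gave 1711 to 2172, and 2081 to 2184 with 1 line left out. Departures (99) were 43 under MAD scaling and 52 under quantile normalization, where the cause was not tested, 36 at an absolute difference of 2 or more by construction, and 33 without lines 10 and 6 together, which removes the line with most calls. With 1 line left out they ranged from 33 (without line 10) to 144 (without line 40), and the other settings gave 84 to 136. With the leading component removed (136), 69 were shared, and the calls of line 10 fell to 47 while those of line 8 rose to 45. List means (13 called) gave 0 with an estimated correlation and 6 by fry. Members of a list correlated across lines, beyond the preset correlation of 0.01. Fry also tests each list against 0 and not against the other genes, so what lowered its count was not separated. Other settings gave 10 to 14 lists, as did leaving out 1 line. Besides the losses given in the report, hexose transporters were called with lines 1 and 45 averaged (adjusted p = 0.0466), without line 16 (0.0484) or without line 45 (0.0354), and adenine genes without line 21 (0.0389) or 44 (0.0324). Chromosome shifts past 0.3 (1) were 2 under MAD scaling and under quantile normalization, where chromosome IX in line 50 reached 0.342 and 0.364. They were 0 with the leading component removed and with means over genes, where chromosome IX in line 49 reached 0.295 in each, just short of the threshold. The leading component held 44.0% of the variance, but 38.0% under MAD scaling and 35.7% under quantile normalization, and the cause was not tested. Lists called for spread (17) ranged from 17 to 23 and for covariation (31) from 31 to 33. Without line 10 the list spread, covariation and chromosome counts were 20, 32 and 1, and the leading component held 44.0%. For spread, ergosterol genes, not called at first, were called in 6 of 6 settings, Hsf1 chaperones in 5 and the glyoxylate list in 2, with other lists gained as well. The median SD of haploid-specific genes reversed, from 0.337 (adjusted p = 0.681), above random lists, to 0.223 without line 10 (adjusted p = 0.0265), below them. The cause was not tested. Of 12446 repeats of single named results, 11568 kept their direction and side of the threshold, 724 fell short of it, 153 newly passed it and 1 reversed. Filters on missing values were not run, because no value was missing, nor was testing every probe on its own, because each feature had 1 value per array. A scaled MAD in place of the SD gave no value, because no gene was called for spread. Signal over background was not used here, so what low signal limits was not examined.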

Other observations

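Chosen only after the result was seen were the tests of stray spots, of opposite signs with a bound of 0.1, of mating type or ploidy, of the leading component for chromosomes, of growth state and of sign flips, and the genes of the next sentences. Line 8 had the lowest values of ZRT1, a zinc transporter gene (-3.99), ADH4 (-2.90) and ZPS1 (-2.02), while its median over the copper and zinc list was 0.03, with 7 of 15 genes above the other lines. It also had the highest values of the glycine cleavage genes GCV1 (2.23) and GCV2 (2.04), of the wall protein gene TIP1 (2.54) and of the drug pump gene PDR5 (2.18). Among list medians, mitochondrial ribosomal proteins (0.76) and oxidative stress genes (0.40) were highest in line 8 and the respiratory chain lowest (-0.62). Line 40 had the highest thiamine median (0.91, lowest in line 44 at -1.03), with THI13 at 2.01 and THI4 at 1.83, and the highest histone median (1.42, lowest in line 7 at -1.22). Line 6 had the lowest SUC2 value (-4.22) beside the highest values of the glucose transporter genes HXT4 (2.40) and HXT1 (2.27), with the lowest stress median (-1.81). None of these single genes passed the departure test in these lines over all features. Lines 1 and 45 were the most similar pair, with r = 0.899 across genes and an SD of their difference of 0.212, where the median pair had 0.475. The labels do not say whether these 2 lines are independent, and if they are not, tests over 23 lines and the sign flips count them as 1 too many.

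The positive mating-type and Ty values of lines 10 and 40 were weighed against 3 explanations. An exchange of the channels of an array would turn its remaining genes against the other lines. Across the 25% of genes with the lowest loading on the leading component, the correlation with the other lines was 0.268 in line 10 and 0.0929 in line 40. The value of line 10 argues against a column of reversed sign. It cannot exclude an exchange at labelling, because a dye effect shared by all arrays would keep its sign and the design had no dye swap. In line 40 an exchange cannot be told apart, because the value lay under the bound of 0.1 set beforehand and yet not below 0. A few stray spots would not move most of a list. Of the 7 a-specific genes, 6 in line 10 and 5 in line 40 lay above the highest of the other 21 lines. Of all genes, 11.8% and 10.5% did (hypergeometric p = 1.64e-05 and 0.000217). Most members were thus high, but both lines were picked by the medians of these genes, so the count largely restates that choice. The p-values also take the genes as independent, although their mean pairwise correlation was 0.457. Stray spots therefore cannot be excluded by this test. This test came after one on the list median had left line 10 undecided (1.31, highest random list 1.38). For the Ty frames, listed after they were seen, stray spots were not tested. The list of 29 genes used next mixes haploid-specific with pheromone-response genes. Its differences in line 10 ran from -0.92 (GPG1) to 3.06 (FAR1), so its median alone cannot decide for or against the last explanation. A mating type or ploidy that differs between line 10 and the reference may be a candidate explanation. Of 29 haploid-specific genes, 5 were among the 68 called genes of line 10, where 0.311 were expected (Fisher's exact p = 1.20e-05). With the leading component removed, 2 of 29 were among 47 (Fisher's exact p = 0.0193). The median of that list, which cannot decide, reached the 84.94th percentile in line 10 and the 99.59th in line 40, where the calls were not tested. This explanation cannot be told apart, because the list is mixed and the labels give neither mating type nor ploidy.

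The chromosome shifts were set against 3 explanations. With the leading component removed, the smallest of the 5 absolute medians was still 0.218, outside random sets, which argues against that component as the whole cause. For chromosome IX in lines 49 and 50, 8 of 8 segments (4 per chromosome, by gene order) lay outside random sets. So did 4 of 4 for chromosome XIII in line 20. This argues against a block of neighbouring genes within 1 segment there, but cannot exclude a wider block or several blocks. Random sets also lack any shared movement of neighbouring genes. A block may hold for chromosomes VI and VIII in line 20, where 6 of 8 segments lay outside. On chromosome VIII the segment inside was borderline (-0.106, lowest random median -0.108). Another copy number of the whole chromosome may explain chromosome IX in line 49 and chromosome XIII in line 20 (where 13 of 16 chromosomes were called without a size threshold, so a pattern of the whole column stays open), where the interquartile range over that of other genes was 1.10 and 1.23, within the bound set beforehand. That ratio was 1.497 for chromosome IX in line 50 and 1.496 for chromosome VIII in line 20, beyond the bound. For chromosome VI in line 20 it was 1.11, but 1 segment lay inside random sets. By these rules a whole-chromosome change alone was not borne out in these cases. It cannot be excluded either, since the segments inside random sets still lay on the side of their chromosome. The ratio does not measure copy number, so it cannot set chromosome IX in line 49 apart from that in line 50. The medians were not set against the size that a copy change would give, since neither ploidy nor the log base is given. Neither DNA measurements nor the print layout were used here.

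The axis of ribosomal protein genes against stress genes was set against 2 explanations. Columns deposited with opposite signs would give correlations below 0 with the other lines over genes of low loading. With the bound of 0.1 used above, in place of the bound of 0 first written, 21 lines, all those at the ends of the axis among them, lay above it (lowest 0.141, line 19), which argues against it there, while lines 40 and 42 (0.0716) cannot be told apart, because their values lay between the bounds. Growth state at harvest may underlie the axis, since stress genes moved with galactose, maltose and sucrose genes (r = 0.863), but it cannot be told apart from a heritable difference between lines, because each line has 1 column and no separate cultures of a line could be compared. For the mean over lines, the signs of whole arrays were flipped at random 100 times. Of these flips, 1 called at least as many genes as the 584 of the real table, with 664 in that flip. The median over the flips was 0. At the 0.05 level this argues against array-wide variation with no common mean as the only source of the calls. The flips took all lines as independent, the most similar pair included. A shared reference culture or a dye effect would give every array a common mean, so the flips cannot address either. No other biological explanation was tested, since the labels give no second group.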
